A study of Mus musculus with 24 samples.

How the data were processed

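The authors' values were used as given. Per the submitters' processing notes, CASAVA 1.8, Bowtie, Cufflinks 2.0.2 and Cuffnorm were used with mouse genome build mm9, with neither the role nor the order of the tools stated. The authors deposited FPKM with 1 line per Ensembl gene. The table's header gives no unit, and FPKM was taken from Cuffnorm, since the values are not whole numbers and library sums differ. The authors' scaling between libraries and the gene annotation release are not given in the sources used here. Values carry 3 significant digits. Per the labels' protocols, poly(A) RNA with RNA integrity numbers of 6.6 to 9.2 was prepared with an earlier or a v2 TruSeq guide and sequenced on a Genome Analyzer IIx. Reads were not analysed here.

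The table held 36806 genes, of which 12784 were at 0 in every library. The reference was used for gene names (31840 of the 36806) and for the order of neighbouring genes. All 24 columns matched a sample title. Replicates were numbered in the order of their accessions, and nothing in the labels pairs animals, so no pairing was used. Each library came from a different animal by the series design. At most 0.96% of values were identical between a pair of libraries, and libraries of a group correlated at r = 0.8795 to 0.949.

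Many abundant genes were listed at exactly 0 in every library of a group and at high values in other groups. Such zeros were treated as missing estimates where each library of another group had at least 100 FPKM, and the same was done for neighbouring genes with the same pattern. This covered 53 genes and 134 combinations of gene and group, and was decided after the values were seen. Where a group was missing, the gene was left out of the comparisons that use it, so no fold change against such zeros is given. A group at 0 in every library below that bound was kept, and calls with such a group numbered 3, 3, 8 and 4 for the genotype differences in saline and at 8, 24 and 48 h, and 31 for their mean. They numbered 26 to 70 for the comparisons of times and 2 to 5 for the interactions, and no fold change is given for them. Ctrb1, Amy2a5 and Amy2b were at 0 in all 24 libraries. The alternative that keeps these zeros is given under the dependence on processing.

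Genes with at least 1 FPKM in at least 3 of the 24 libraries were tested. The unit of analysis was log2(FPKM + 1). A model with 1 mean per group (16 residual degrees of freedom) was fitted with limma 3.58.1 in R 4.3.3, with trend and robust empirical Bayes moderation, and 16 contrasts were tested, each with Benjamini-Hochberg adjustment over its genes. Tests were two-sided. Comparisons, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

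Named genes were chosen by rule. The rule took Nr5a2, up to 8 genes per direction with the largest fold change among those past the threshold with an official symbol, a mean of at least 1 FPKM in the higher group and values that did not overlap between the compared groups (for the mean difference, the same sign in all 4 conditions). It also took up to 4 members per described list with the smallest adjusted p, or 2 members as values only where none passed. Some genes chosen by this rule are not reported here, and the counts of named genes include them. The 32 gene lists were digestive enzymes and other acinar secretory products, acinar transcription factors, Reg family, duct markers, acinar dedifferentiation markers, AP-1 and immediate early genes, chemokines and cytokines, complement, acute phase genes, interferon-response genes, MHC class II genes, unfolded protein and amino acid stress response, heat shock genes, cell cycle, p53 targets, cholesterol synthesis, ribosomal protein genes, circadian clock genes, replication-dependent histones, sex-linked transcripts, and markers of macrophages, neutrophils, B cells, T cells, fibroblasts and stellate cells, endothelium, islets, adipocytes, intestinal epithelium, red blood cells, mesothelium and Schwann cells. Camera and fry used the members with values in all 8 groups, fewer than the members tested singly for the enzyme list. All but the sex-linked list were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. Of 496 tests camera called 199, fry 155 and both 124, and camera with an estimated correlation called 1. For the saline genotype difference, the 1 comparison tried, shuffling residuals 100 times left at least 1 list called by camera in 98 shuffles (highest 22 lists), by camera with an estimated correlation in 2 and by fry in 5.

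Simulated changes in 200 of 12835 genes showed what the design could detect. For the saline genotype difference 26.4% of changes of 1.5-fold, 65.5% of 2-fold and 93.2% of 4-fold were recovered, with 6.1 false calls per run. For the mean genotype difference the shares were 77.5, 95.8 and 98.5%, and for the 24 h interaction 5.8, 34.5 and 84.1%.

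Correlations between sets of fold changes were set beside 1000 simulations that kept the shared control libraries, or, for genotype differences at separate times, beside all 200 exchanges of genotype labels. Groupings of the libraries were fitted in full, with the real one counted among them. These were all 10 for 3 animals against 3, and 100 for the mean difference and interactions, where the others were drawn at random. Alternatives changed 1 choice at a time, among them the pseudocount (0.1), the filter, median-of-ratios and quantile scaling, scaling to the total without enzyme and Reg genes, a spread from the compared groups alone, a sex covariate and each library left out.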

Results

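Polyadenylated RNA of whole pancreas was measured by RNA sequencing in C57BL mice with 2 intact copies of Nr5a2 (+/+, called WT) and in mice with 1 (+/-, called HET). Nr5a2 encodes a nuclear receptor that regulates digestive enzyme genes in acinar cells, the enzyme-secreting cells that make up most of the pancreas. The mice received saline or 7 hourly injections of caerulein, a cholecystokinin analog that overstimulates acinar cells and causes a mild acute pancreatitis. Caerulein-treated mice were killed 8, 24 or 48 h after the first injection. The 8 groups of genotype and treatment held 3 animals each, 24 libraries in all. Values are the authors' FPKM (fragments per kilobase of transcript, scaled to library size), so the sequencing depth of each library is unknown and no counting error can be given. The FPKM of all genes summed to 866120 to 1007572 per library in WT saline, 479172 to 664626 in WT at 8 h, 390241 to 435002 at 24 h and 394906 to 688666 at 48 h. In HET the sums were 745601, 755744 and, in replicate 1, the highest of all libraries in saline, 460255 to 551933 at 8 h, and 253085 to 282830 at 24 h. At 48 h they were 279109, 273207 and, in replicate 3, the lowest of all libraries.

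Fold changes are differences of group means of log2(FPKM + 1), given with their standard error. This scale understates the change of genes expressed at a few FPKM or less. FPKM values are mean ± SD of 3 animals. Between 12835 and 12867 genes were tested per comparison with limma, at an adjusted p threshold of 0.05 over all genes of the comparison. "Rose", "fell", "higher" and "lower" are used of genes past that threshold. Counts for a gene list are given over all genes and, in addition, with p adjusted over the members of the list alone. The list test camera, with its preset correlation of 0.01 between genes, called a median of 10 of 31 lists when residuals were shuffled so that no group effect was left, a trial made for the saline genotype difference alone. Its result with an estimated correlation is therefore given beside it.

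Libraries of the saline and 24 h groups were prepared under an earlier guide with 10 cycles of PCR, those of the 8 h and 48 h groups under a v2 guide with 8 cycles. Changes from saline to 8 h or 48 h hence hold the change of guide as well as time. A change of guide alone would move the 8 h and 48 h libraries alike, so 48 h against 8 h, within the v2 guide, is set beside them. Genotype differences, 24 h against saline and 48 h against 8 h are within one guide. WT_saline replicate 3 stands in neither list of library names.

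Nr5a2 (ENSMUSG00000026398) was measured first, as the gene whose copy number differed. Its FPKM was 12.6, 9.26 and 10.2 in the WT saline libraries and 9.09, 8.01 and 8.79 in the HET saline libraries. At 8 h the values were 3.2, 2.25 and 2.78 in WT and 2.15, 1.88 and 2.1 in HET. At 24 h they were 4.64, 5.48 and 6.44 in WT and 4.09, 5.39 and 4.33 in HET, and at 48 h 6.06, 4.08 and 6.2 and 5.7, 3.75 and 2.64. The ranges of the genotypes did not overlap at saline and 8 h and overlapped at 24 h and 48 h. For 3 animals against 3, chance alone separates the ranges in 10% of cases. No single condition gave a difference past the threshold, with log2 fold changes of −0.27 ± 0.19, adjusted p = 0.448 in saline, −0.29 ± 0.19 at 8 h, −0.22 ± 0.19 at 24 h and −0.39 ± 0.19 at 48 h. Averaged over the 4 conditions Nr5a2 was lower in HET (−0.29 ± 0.09, adjusted p = 0.0368), a call that ended in 14 of the 24 fits that left out 1 library (adjusted p = 0.0714 without WT_48h replicate 3) and under scaling to the total without enzyme and Reg genes (−0.12, adjusted p = 0.542). The same scaling turned the 48 h value to 0.02 (adjusted p = 0.97, with 0.147 to 0.97 over the alternatives). Nr5a2 changed with caerulein too. It fell at 8 h in WT (−1.64 ± 0.19, adjusted p = 5.16e-07) and in HET (−1.66 ± 0.19, adjusted p = 3.89e-07). It stayed below saline in WT at 24 h (−0.84 ± 0.19) and 48 h (−0.87 ± 0.19) and in HET at both times (−0.79 ± 0.19 and −0.98 ± 0.19). Whether the intact allele or the targeted allele gave the remaining transcript cannot be read from values per gene.

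**Figure D1:**
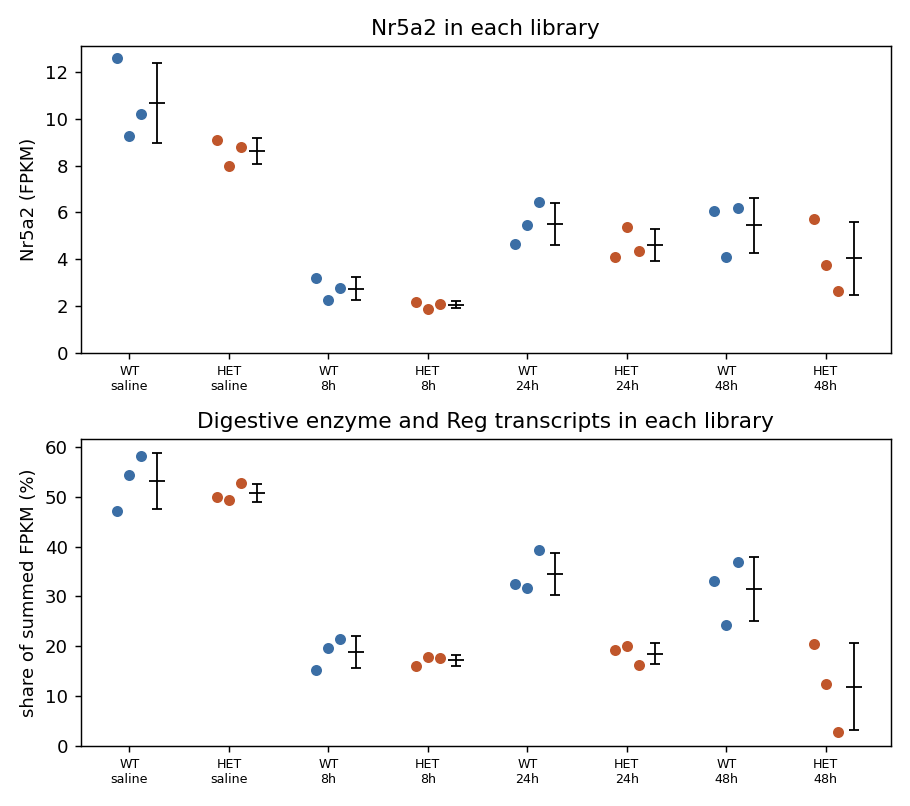
Nr5a2 in FPKM (top) and the share of digestive enzyme and Reg family genes in the summed FPKM of a library in percent (bottom) are plotted per library as points for the 8 groups, with the mean and SD of 3 animals. The share was taken over the genes with values in all 8 groups, because abundant enzyme genes such as Cel and Pnlip were listed at 0 in some groups. It was 47.17 to 58.16% in the saline libraries and 2.8% in HET_48h replicate 3.

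Comparing genotypes in saline-treated mice asked what 1 missing copy of Nr5a2 changed before injury. Of 12857 genes, 148 were higher and 155 lower in HET. Scd1, which desaturates fatty acids, measured 13.1 ± 7.42 FPKM in WT and 133 ± 92.9 FPKM in HET (log2 fold change 3.16 ± 0.71, adjusted p = 0.0275). Fasn, the fatty acid synthase, measured 12.8 ± 2.79 and 84.3 ± 40.4 FPKM (2.55 ± 0.36, adjusted p = 0.00106). Me1, which makes NADPH for fatty acid synthesis (2.59 ± 0.35), Dgat2 of triglyceride synthesis (2.48 ± 0.55) and the lipogenic regulator Thrsp (3.11 ± 0.61) were higher too. So were the adipocyte hormone gene Retn (3.05 ± 0.75), the transferrin gene Trf (2.51 ± 0.64) and the chemokine gene Ccl8 (2.71 ± 0.65). Lower in HET was Ppp1r1b, a regulator of protein phosphatase 1 (13.2 ± 1.54 against 2.65 ± 1.39 FPKM, log2 fold change −2.02 ± 0.24, adjusted p = 0.000564). Il4i1, an L-amino acid oxidase, measured 9.03 ± 3.34 and 1.1 ± 0.682 FPKM (−2.24 ± 0.30). The kallikrein-related gene Klk1b11 (−1.89 ± 0.41), the secretory granule gene Scg3 (−1.54 ± 0.33), the lipid carrier Apod (−1.50 ± 0.35), the receptor gene Notch1 (−1.49 ± 0.37), Hyi (−1.48 ± 0.32) and the antisense transcript Usp46os2 (−1.51 ± 0.21) were lower as well.

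Of 12 adipocyte markers tested, Thrsp and Retn passed over all genes and 10 rose when adjusted over the list alone, with a median log2 fold change of 2.29 (camera adjusted p = 1.1e-08, adjusted p = 0.35 with an estimated correlation). The mean log2(FPKM + 1) of the adipocyte list was 0.83, 2.41 and 2.11 in the WT saline libraries and 3.35, 4.67 and 4.04 in the HET saline libraries. That of the B cell list was 0.28, 0.41 and 1.57 in WT and 0.99, 2.15 and 1.94 in HET. Among 19 macrophage markers Tyrobp, a signalling adaptor of myeloid cells, was higher (1.91 ± 0.37, adjusted p = 0.0115), and 8 passed over the list alone (camera adjusted p = 1.48e-08, adjusted p = 0.35 with an estimated correlation). Of 19 fibroblast and stellate cell markers, 3 were higher, the intermediate filament gene Vim (1.64 ± 0.32) and the matrix genes Sparc (0.99 ± 0.23) and Postn (1.42 ± 0.36). Adjusted over the list alone, 9 passed (camera adjusted p = 1.42e-08, adjusted p = 0.35 with an estimated correlation). Of 31 cell cycle genes, 3 were higher, Mcm5 of the replicative helicase (1.03 ± 0.23), Birc5 of mitosis (0.98 ± 0.25) and the sliding clamp Pcna (0.55 ± 0.14). Over the list alone 12 were higher (camera adjusted p = 1.1e-08, adjusted p = 0.35 with an estimated correlation). Of 17 markers of acinar dedifferentiation, 4 were higher, Lgals3 (1.79 ± 0.38), Anxa2 (1.32 ± 0.23), S100a6 (1.22 ± 0.22) and S100a11 (1.08 ± 0.16). With the list alone 6 were higher and 1 lower (camera adjusted p = 0.00751, adjusted p = 0.35 with an estimated correlation). Islet markers moved the other way, with Pcsk2, a prohormone convertase, lower (−1.35 ± 0.35, adjusted p = 0.048). Over the list alone 13 of 14 members were lower, at a median of −1.32 (camera adjusted p = 7.75e-08, adjusted p = 0.35 with an estimated correlation). None of 17 digestive enzyme genes and none of 11 acinar transcription factor genes tested passed.

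The count of 303 fell to 117 without HET_saline replicate 2, 150 without WT_saline replicate 1 and 192 without WT_saline replicate 3, and to 1 when the spread was taken from the compared groups alone. It was 11 when libraries were scaled to their total without enzyme and Reg genes and 9 with the adipocyte and B cell list means as covariates. 9 of the 28 named genes past the threshold kept their call without any one library (Me1, Fasn, Il4i1, Ppp1r1b, Usp46os2, S100a11, Anxa2, S100a6 and Tyrobp), and the call of each other named gene ended without at least 1.

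At 8 h the comparison of genotypes asked whether HET pancreas differed while injury was beginning. Few genes differed, 22 higher and 6 lower of 12859, a split that was 1 and 4 with a pseudocount of 0.1 and 2 and 2 with the spread of the compared groups alone. The acute inflammatory gene Ptx3, a soluble pattern recognition protein, measured 11.3 ± 3.6 FPKM in WT and 43 ± 16.6 FPKM in HET (log2 fold change 1.82 ± 0.32, adjusted p = 0.0164). The cytokine gene Il6 measured 0.781 ± 0.756 and 4.8 ± 0.959 FPKM (1.78 ± 0.28, adjusted p = 0.00783), and the neutrophil chemokine gene Cxcl2 0.924 ± 0.443 and 4.49 ± 0.586 FPKM (1.53 ± 0.30). Fam107b (1.81 ± 0.36), the small GTPase Rrad (1.77 ± 0.27), the immediate early gene Arc (1.32 ± 0.26) and the hyaluronan synthase Has1 (1.19 ± 0.22) were higher. Lower were the growth factor Pgf (10.2 ± 4.06 against 1.56 ± 0.363 FPKM, log2 fold change −2.07 ± 0.34, adjusted p = 0.00861), the epoxide hydrolase Ephx1 (−0.84 ± 0.15), the receptor Acvr1c (−0.78 ± 0.16) and the guidance cue Ntn1 (−0.72 ± 0.15).

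Il6 and Cxcl2 were the 2 of 24 chemokine and cytokine genes that passed, and 9 rose with p adjusted over the list alone (median 0.68, camera adjusted p = 5.13e-14, adjusted p = 0.396 with an estimated correlation). Of 11 neutrophil markers 2 were higher, the collagenase Mmp8 (1.16 ± 0.17, adjusted p = 0.00357) and the receptor Trem1 (1.06 ± 0.20). Over the list alone 3 were higher (camera adjusted p = 6.84e-07, adjusted p = 0.605 with an estimated correlation). None of 19 macrophage markers passed (median 0.70, camera adjusted p = 5.27e-07, adjusted p = 0.605 with an estimated correlation), with Lyz2 at 96.5 ± 42.4 FPKM in WT and 203 ± 39.6 FPKM in HET.

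Without HET_8h replicate 1, 5 genes were called (4 of the 28), without WT_8h replicate 3 or HET_8h replicate 3, 9 each (7 and 8 of the 28), and without HET_8h replicate 2, 16. Scaling to the total without enzyme and Reg genes left 10 (9 higher, 1 lower). Mmp8 was the only one of 13 named genes that stayed past the threshold without any one library.

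At 24 h, when inflammation was established, the genotypes were compared again, and 453 genes were higher and 388 lower in HET of 12844. The tight junction gene Cldn4 measured 26.6 ± 12.6 FPKM in WT and 244 ± 16.6 FPKM in HET (log2 fold change 3.24 ± 0.45, adjusted p = 0.000678). Higher too were the macrophage product Chil3 (36.4 ± 32.2 against 189 ± 79.2 FPKM, 2.81 ± 0.80, adjusted p = 0.0427) and the monocyte chemokine Ccl12 (2.65 ± 0.57). The cytokine Ltb (2.60 ± 0.41), the interleukin 1 receptor antagonist Il1rn (2.55 ± 0.49) and the chemokine Cxcl14 (2.15 ± 0.28) were higher as well. So were the metalloproteinase Mmp7 (2.13 ± 0.46) and Wfdc18 (2.09 ± 0.34). Bhlha15 encodes Mist1, the transcription factor that builds the secretory apparatus of acinar cells, and measured 16.8 ± 4.87 FPKM in WT and 0.674 ± 0.243 FPKM in HET (log2 fold change −3.39 ± 0.46, adjusted p = 0.000619). The pancreatic ribonuclease Rnase1 measured 5750 ± 740 and 651 ± 133 FPKM (−3.15 ± 0.80, adjusted p = 0.0232). The cholecystokinin receptor Cckar, on which caerulein acts, measured 132 ± 15.5 and 25.6 ± 8.18 FPKM (−2.36 ± 0.40). Serpini2, a protease inhibitor of acinar cells (−3.44 ± 0.92), the kallikrein-related Klk1b11 (−3.31 ± 0.41), the ribonuclease Ang (−2.82 ± 0.36) and the claudin Cldn10 (−2.58 ± 0.39) were lower too.

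Of 11 acinar transcription factor genes 3 were lower, Bhlha15, Rbpjl of the PTF1 complex (−2.05 ± 0.39, adjusted p = 0.00418) and the NR5A2 target Nr0b2 (−1.50 ± 0.31), and Hnf4a was higher (0.96 ± 0.20). Over the list alone 5 were lower and 1 higher (camera adjusted p = 0.0104, adjusted p = 0.651 with an estimated correlation), and the camera call ended without WT_24h replicate 3 (adjusted p = 0.0532). Rnase1 was the only one of 22 digestive enzyme and secretory product genes past the threshold, at a median of −1.38 (camera adjusted p = 7.58e-05, adjusted p = 0.651 with an estimated correlation). Several enzyme genes, Cela1 and Prss2 among them, could not be tested because the table listed them at 0 in a group. Over genes with values in all 8 groups, enzyme and Reg genes made up 31.61 to 39.41% of summed FPKM in the WT 24 h libraries and 16.15 to 20.13% in the HET 24 h libraries. Of 23 genes of the unfolded protein and amino acid response 3 were lower, all of degradation from the endoplasmic reticulum, Sel1l (−2.21 ± 0.34), Edem1 (−0.93 ± 0.21) and Herpud1 (−1.12 ± 0.27). The list as a whole was not called (camera adjusted p = 0.174, adjusted p = 0.826 with an estimated correlation). Of 16 dedifferentiation markers 6 were higher, with Cldn4, S100a11 (1.43 ± 0.16), Anxa3 (1.28 ± 0.22) and the keratin Krt8 (1.11 ± 0.25) the clearest. Within the list alone 7 were higher (camera adjusted p = 0.00652, adjusted p = 0.45 with an estimated correlation). Of 24 chemokine and cytokine genes 7 were higher over all genes and over the list alone (camera adjusted p = 8.86e-05, adjusted p = 0.651 with an estimated correlation). Among them were Cxcl16 (1.57 ± 0.24) and the monocyte attractants Ccl7 (1.42 ± 0.30) and Ccl2 (1.52 ± 0.35). Of 17 genes of cholesterol synthesis 5 were higher, with Cyp51 (1.05 ± 0.26), Msmo1 (0.98 ± 0.25) and Sc5d (0.59 ± 0.15). Over the list alone 6 were higher (camera adjusted p = 3.3e-06, adjusted p = 0.45 with an estimated correlation).

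The count of 841 fell to 309 without HET_24h replicate 1, 412 without WT_24h replicate 2, 474 without HET_24h replicate 2, 495 without HET_24h replicate 3 and 258 (109 higher, 149 lower) with the spread of the compared groups alone. It was 528 (361 higher, 167 lower) when scaled to the total without enzyme and Reg genes. 18 of the 32 named genes kept their call without any one library, and among those that did not were Chil3, Ccl12, Mmp7, Serpini2, Rnase1, Krt8, Ccl7, Ccl2, Edem1, Herpud1, Cyp51, Sc5d and Msmo1.

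At 48 h the comparison asked whether HET pancreas recovered as WT pancreas did, and 753 genes were higher and 819 lower of 12867. The chymotrypsin-like protease Ctrl measured 12400 ± 5520 FPKM in WT and 1000 ± 993 FPKM in HET (log2 fold change −4.68 ± 0.82, adjusted p = 0.00114). The zymogen granule lectin Zg16 measured 7140 ± 2940 and 695 ± 701 FPKM (−4.63 ± 0.90, adjusted p = 0.00283). The bile salt-activated lipase Cel measured 9750 ± 4380 and 1060 ± 1080 FPKM (−4.46 ± 1.20), and the pancreatic lipase Pnlip 13600 ± 7850 and 1220 ± 1300 FPKM (−4.41 ± 1.13). The neuropeptide gene Gal (−4.77 ± 0.73, adjusted p = 0.000547), the cargo receptor Tmed11 (−4.54 ± 0.47), the protease inhibitor Serpini2 (−4.32 ± 0.92) and the pancreas-specific disulfide isomerase Pdia2 (−4.23 ± 0.71) were lower to a similar degree. Higher in HET were Cldn4 (31 ± 29.5 against 133 ± 53.6 FPKM, 2.38 ± 0.45, adjusted p = 0.00239) and Il1rn (2.20 ± 0.49). Also higher were the protease inhibitor Serpinb6b (2.13 ± 0.38), Wfdc17 (2.06 ± 0.55), the metalloproteinases Mmp7 (2.05 ± 0.46) and Mmp3 (1.99 ± 0.36), the macrophage Fc receptor Fcgr1 (1.98 ± 0.47) and the retinoic acid-producing enzyme Aldh1a2 (1.96 ± 0.35).

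All 24 tested genes of digestive enzymes and secretory products were lower over the list alone and 21 over all genes, at a median of −3.59 (camera adjusted p = 1.24e-16, adjusted p = 0.393 with an estimated correlation). Without HET_48h replicate 3 the median was −2.3 and 20 of the 24 still passed. Sycn of the zymogen granule (−4.19 ± 0.68), Klk1 (−3.78 ± 0.62) and the trypsinogen Prss1 (−2.71 ± 0.46) were among them. HET_48h replicate 3 stood apart, with 2.8% of its summed FPKM in enzyme and Reg genes, over genes with values in all 8 groups, against 20.37 and 12.51% in the other HET and 24.37 to 36.99% in the WT 48 h libraries. Of 11 acinar transcription factor genes 6 were lower and 7 over the list alone (camera adjusted p = 1.34e-05, adjusted p = 0.393 with an estimated correlation). Bhlha15 (−3.51 ± 0.46), Rbpjl (−2.81 ± 0.39), Ptf1a (−1.49 ± 0.43) and Nr0b2 (−1.28 ± 0.31) were among them. Reg1 (−2.34 ± 0.57) and Reg3d (−2.71 ± 0.72) were the 2 of 6 Reg family genes that were lower (camera adjusted p = 0.00376, adjusted p = 0.432 with an estimated correlation), and the camera call ended with quantile scaling (adjusted p = 0.163). Of 23 unfolded protein and amino acid response genes 11 were lower, with Sel1l (−2.19 ± 0.34), Edem1 (−1.54 ± 0.21), Herpud1 (−1.52 ± 0.27) and the asparagine synthetase Asns (−1.25 ± 0.26). Within the list alone 12 were lower (camera adjusted p = 1.42e-06, adjusted p = 0.404 with an estimated correlation). Of 26 ribosomal protein genes 14 were lower, Rpl3 (−0.76 ± 0.22) and Rps18 (−0.82 ± 0.24) among them, and 25 over the list alone (camera adjusted p = 1.37e-11, adjusted p = 0.404 with an estimated correlation).

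Other lists were higher in HET at 48 h. Of 31 cell cycle genes 17 were higher and 24 over the list alone (camera adjusted p = 2.78e-11, adjusted p = 0.393 with an estimated correlation). Among them were Birc5 (1.43 ± 0.25), the cyclin Ccna2 (0.94 ± 0.19), the transcription factor Foxm1 (0.85 ± 0.19) and Mcm5 (1.02 ± 0.23). Of 19 macrophage markers 10 were higher and 14 over the list alone, with the mannose receptor Mrc1 (1.51 ± 0.34), Cd14 (1.88 ± 0.45) and Cx3cr1 (0.98 ± 0.23) beside Fcgr1 (camera adjusted p = 1.93e-07, adjusted p = 0.404 with an estimated correlation). The mean log2(FPKM + 1) of that list was 2.98, 4.68 and 3.91 in the WT and 4.61, 5.25 and 5.27 in the HET 48 h libraries. Of 24 chemokine and cytokine genes 6 were higher and 9 over the list alone (camera adjusted p = 0.000148, adjusted p = 0.432 with an estimated correlation). Among them were Cxcl5 (1.68 ± 0.44), Cxcl16 (1.45 ± 0.24), Cxcl14 (1.35 ± 0.28) and Tnf (0.89 ± 0.22). Of 19 fibroblast markers 5 were higher and 7 over the list alone, with the collagens Col1a1 (1.41 ± 0.35) and Col3a1 (1.22 ± 0.36) and the inhibitor Timp1 (1.8 ± 0.40) (camera adjusted p = 0.0361, adjusted p = 0.704 with an estimated correlation). Of 17 dedifferentiation markers 6 were higher, S100a11 (1.15 ± 0.16) and Anxa3 (1.14 ± 0.22) with Cldn4, and 2 were lower, with the trefoil factor Tff2 at −3.12 ± 0.64 (camera adjusted p = 0.041, adjusted p = 0.404 with an estimated correlation). The camera calls of the fibroblast and dedifferentiation lists ended under scaling to the total without enzyme and Reg genes and without single 48 h libraries. Of 12 endothelial markers 3 were lower, Pecam1 (−0.87 ± 0.21), Plvap (−0.65 ± 0.21) and Kdr (−0.53 ± 0.17), and 4 over the list alone (camera adjusted p = 0.00114, adjusted p = 0.404 with an estimated correlation).

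The count of 1572 fell to 474 without WT_48h replicate 1, 487 without HET_48h replicate 3, 657 without WT_48h replicate 3, and 868 without HET_48h replicate 2. It was 28 with the spread of the compared groups alone and 487 without WT_48h replicates 1 and 2, which held Xist with Y-linked transcripts, where 1 WT library was left and the other groups gave the spread. Scaled to the total without enzyme and Reg genes it was 3509 (3179 higher, 330 lower). 27 of the 55 named genes kept their call without any one library, among them Cldn4, Serpinb6b, Mmp3, Aldh1a2, Gal, Ctrl, Zg16, Tmed11, Serpini2, Pdia2, Sycn, Klk1, Prss1, Bhlha15, Rbpjl, S100a11, Anxa3, Tff2, Cxcl16, Cxcl14, Edem1, Sel1l, Herpud1, Asns, Birc5 and Ccna2.

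**Figure D2:**
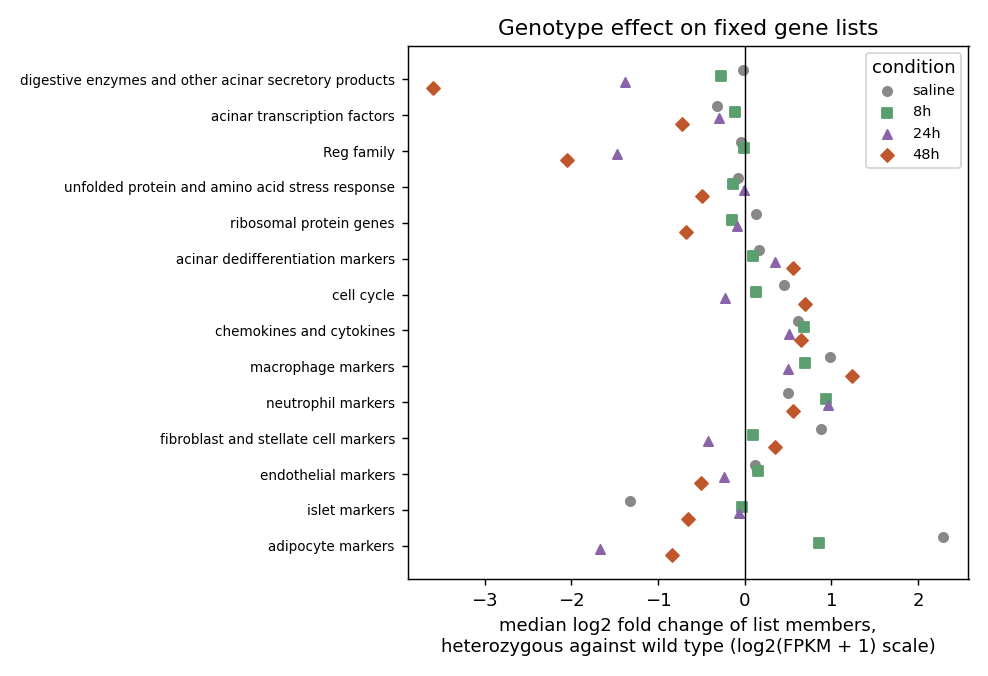
The median log2 fold change of HET against WT, on the log2(FPKM + 1) scale, is plotted for 14 gene lists as 1 point per list and condition. The digestive enzyme list stood at −0.03 in saline and −3.59 at 48 h (−2.3 without HET_48h replicate 3) over the members tested at each time, −0.04 and −3.67 over the 16 with values in every group, and the adipocyte list at 2.29 in saline.

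Averaging the genotype difference over the 4 conditions asked what 1 missing copy of Nr5a2 changed on average, with 12 animals per genotype. Of 12835 genes, 1315 were higher and 1077 lower in HET. Lower were the chymotrypsin-like Ctrc (−2.44 ± 0.64, adjusted p = 0.0128) and Ctrl (−1.93 ± 0.41, adjusted p = 0.0029) and the granule gene Sycn (−1.81 ± 0.34). The kallikrein-related Klk1b11 (−2.40 ± 0.20) and Klk1b5 (−2.03 ± 0.23), the transcription factor Bhlha15 (−1.87 ± 0.23, adjusted p = 6.37e-05), the cargo receptor Tmed11 (−1.73 ± 0.23) and the neuropeptide Gal (−2.18 ± 0.37) were lower as well. Ctrc varied widely between animals, at 12500, 609 and 413 FPKM in the WT saline libraries. Higher were the calprotectin subunit S100a8 (1.8 ± 0.54, adjusted p = 0.0262), Chil3 (1.78 ± 0.40), the arginase Arg1 (1.72 ± 0.45) and the chemokine Ccl6 (1.58 ± 0.36). Il1rn (1.49 ± 0.25), the cytokine Il1b (1.46 ± 0.31), Mmp7 (1.46 ± 0.23) and the matrix protein Tgfbi (1.45 ± 0.21, adjusted p = 0.000177) were higher too.

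Of 16 digestive enzyme genes tested 14 were lower and all 16 over the list alone (camera adjusted p = 8.92e-10, adjusted p = 0.424 with an estimated correlation), among them Prss1 (−1.23 ± 0.23) and Klk1 (−1.56 ± 0.31). The medians of these 16 were −0.04 in saline, −0.30 at 8 h, −1.18 at 24 h and −3.67 at 48 h, and no member passed in saline or at 8 h. Of 11 acinar transcription factors 5 were lower and 7 over the list alone, with Rbpjl (−1.41 ± 0.19), Ptf1a (−1.06 ± 0.22) and Nr0b2 (−0.77 ± 0.16) (camera adjusted p = 0.000255, adjusted p = 0.424 with an estimated correlation). Of 23 unfolded protein and amino acid response genes 6 were lower, with Sel1l (−1.24 ± 0.17) and the stress sensor Ern1 (−0.40 ± 0.06) (camera adjusted p = 0.000594, adjusted p = 0.569 with an estimated correlation). Of 19 macrophage markers 17 were higher and 18 over the list alone, with Tyrobp (1.33 ± 0.18), Ccr2 (1.23 ± 0.21) and Cd14 (1.20 ± 0.22) (camera adjusted p = 2e-10, adjusted p = 0.424 with an estimated correlation). Of 24 chemokine and cytokine genes 16 were higher and 17 over the list alone, with Ccl2 (1.16 ± 0.18), Ccl7 (1.16 ± 0.15) and Cxcl16 (1.10 ± 0.12) (camera adjusted p = 2e-10, adjusted p = 0.424 with an estimated correlation). Of 11 neutrophil markers 5 were higher and 9 over the list alone, with Mmp8 (0.56 ± 0.08) and Csf3r (0.85 ± 0.23) (camera adjusted p = 0.000305, adjusted p = 0.472 with an estimated correlation). Of 16 dedifferentiation markers 9 were higher and 2 lower, with S100a11 (0.93 ± 0.08), Anxa2 (0.76 ± 0.11) and Cldn4 (1.40 ± 0.23) (camera adjusted p = 0.0012, adjusted p = 0.424 with an estimated correlation). Of 31 cell cycle genes 11 were higher and 15 over the list alone, with Birc5 (0.69 ± 0.13) and Mcm4 (0.42 ± 0.10) (camera adjusted p = 5.68e-07, adjusted p = 0.442 with an estimated correlation).

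No left-out library and no other setting moved the count of 2392 by more than 1.5 times, although scaling to the total without enzyme and Reg genes turned the split to 2662 higher and 375 lower. 44 of the 46 named genes kept their call without any one library, all but S100a8 and Nr5a2.

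Changes from saline to 8 h asked how the pancreas answered caerulein early. In WT 3621 genes rose and 2933 fell, and in HET 3949 and 3154. Rcan1, a feedback inhibitor of calcineurin, rose in WT from 5.08 ± 1.3 to 1250 ± 107 FPKM (log2 fold change 7.71 ± 0.17, adjusted p = 4.87e-17). The keratin Krt8 rose from 76.9 ± 6.16 to 5300 ± 176 FPKM (6.09 ± 0.25, adjusted p = 4.12e-13). Also up in WT were the stress factor Atf3 (6.96 ± 0.24), the inositol kinase Itpkc (6.47 ± 0.29), Gclc of glutathione synthesis (6.08 ± 0.23), the TWEAK receptor Tnfrsf12a (5.97 ± 0.27), the actin Actg1 (5.89 ± 0.21) and Kel (7.45 ± 0.29). Cckar fell from 209 ± 13.5 to 4.39 ± 1.67 FPKM (−5.33 ± 0.40, adjusted p = 1.46e-09). Sostdc1 (−5.37 ± 0.39), Rnase1 (−4.33 ± 0.80), the creatine pathway gene Gatm (−4.16 ± 0.29), Tmem97 (−3.96 ± 0.40), Sephs2 of selenoprotein synthesis (−3.77 ± 0.25), Reg2 (−4.57 ± 1.07) and Reg3a (−4.52 ± 1.15) fell too. Of 20 AP-1 and immediate early genes 13 rose over all genes and over the list alone, with Fosl1 (listed at 0 in WT saline and at 7.16 ± 1.19 FPKM at 8 h) and Maff (2.98 ± 0.19) (camera adjusted p = 4.02e-05, adjusted p = 0.976 with an estimated correlation). Of 11 heat shock genes 10 rose by both counts, with Hspa1a (3.02 ± 0.25) and Hspb1 (3.07 ± 0.18) (camera adjusted p = 6.74e-05, adjusted p = 0.449 with an estimated correlation). Of 17 dedifferentiation markers 12 rose and 2 fell, with Krt18 (4.71 ± 0.23) and Anxa2 (3.03 ± 0.23) (camera adjusted p = 0.000841, adjusted p = 0.259 with an estimated correlation). The p53 target list held 5 that rose, Gadd45a (3.83 ± 0.23) and Cdkn1a (3.79 ± 0.36) among them, and 2 that fell, Plk2 (−2.21 ± 0.26) one of them, of 12 (camera adjusted p = 0.268, adjusted p = 0.976 with an estimated correlation). The unfolded protein and amino acid response list split (camera adjusted p = 0.19, adjusted p = 0.976 with an estimated correlation). Chac1 (5.504 ± 0.46) and Trib3 (5.21 ± 0.48) were among 8 that rose and Dnajb11 (−2.78 ± 0.23) among 14 that fell of 23. All 6 Reg family genes fell (camera adjusted p = 0.0214, adjusted p = 0.976 with an estimated correlation), and camera no longer called them with quantile scaling or without WT_8h replicate 1 (largest adjusted p = 0.0752). Of 12 endothelial markers 8 fell and 9 over the list alone, with Kdr (−0.81 ± 0.17) and Plvap (−0.91 ± 0.21) (camera adjusted p = 0.0214, adjusted p = 0.976 with an estimated correlation).

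In HET the largest changes at 8 h included Rcan1 (7.35 ± 0.17, adjusted p = 1.26e-16), Itpkc (7.002 ± 0.29), Kel (6.83 ± 0.29), Atf3 (6.16 ± 0.24), Krt8 (5.94 ± 0.25), Gclc (5.93 ± 0.23), the phosphatase Dusp5 (5.86 ± 0.24) and Cldn4 (6.81 ± 0.45, adjusted p = 3.11e-10), all up. Cckar (−5.36 ± 0.40), Sostdc1 (−4.43 ± 0.39), Rnase1 (−4.32 ± 0.80), Hamp2 (−4.08 ± 0.51), Tmem97 (−3.97 ± 0.40), Reg2 (−4.17 ± 1.07), Reg3a (−4.42 ± 1.15) and Reg3g (−4.33 ± 0.83) fell. Of 20 AP-1 and immediate early genes 12 rose, with Fosl1 (listed at 0 in HET saline and at 9.8 ± 1 FPKM at 8 h) and Klf6 (4.30 ± 0.41) (camera adjusted p = 0.000466, adjusted p = 0.896 with an estimated correlation). Of 11 heat shock genes 10 rose, with Hsp90aa1 (2.97 ± 0.22) (camera adjusted p = 0.000127, adjusted p = 0.443 with an estimated correlation). Of 17 dedifferentiation markers 11 rose and 2 fell (camera adjusted p = 0.00262, adjusted p = 0.443 with an estimated correlation). All 6 Reg genes fell (camera adjusted p = 0.0251, adjusted p = 0.896 with an estimated correlation), a camera call that ended with quantile scaling and without HET_saline replicate 3 (largest adjusted p = 0.0822). Both responses correlated across genes (r = 0.864), and genotype and 8 h interacted in 3 genes. Of the genes that rose at 8 h, 2867 of 3621 in WT and 2739 of 3949 in HET fell again by 48 h within the v2 guide, and of those that fell 1741 of 2933 and 1538 of 3154 rose again. These counts were made after the data were seen, and both comparisons behind them use the 8 h libraries. The change of guide alone does not give the return of such genes, Rcan1, Kel, Itpkc and Krt8 among them. The part of the guide in the step from saline to 8 h cannot be separated for any gene. All named genes of both comparisons kept their calls without any one library.

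Within the earlier preparation guide, 24 h against saline asked what marked established inflammation. In WT 2627 genes rose and 2386 fell. The antimicrobial lectin Reg3g rose from 61.6 ± 51 to 2790 ± 1230 FPKM (5.85 ± 0.83, adjusted p = 3.68e-05). Reg3b rose from 1330 ± 1130 to 19700 ± 7740 FPKM (4.44 ± 0.89), and 3 of 6 Reg genes rose in all (camera adjusted p = 0.174, adjusted p = 0.589 with an estimated correlation). Also up were the chemokines Ccl9 (4.54 ± 0.89) and Ccl7 (3.81 ± 0.30), the protease inhibitor Timp1 (4.29 ± 0.40), the lectin Lgals3 (4.21 ± 0.38) and the iron-binding Lcn2 (3.93 ± 0.45). The pseudogene Rpl39-ps, listed at 0 in the WT saline libraries, measured 41.5, 24.4 and 9.86 FPKM. The secretory pathway genes Tmed11 (−5.55 ± 0.47, adjusted p = 1.66e-07), Fkbp11 (−4.42 ± 0.36) and Derl3 (−4.37 ± 0.36) fell. So did Hamp2 (−5.31 ± 0.51), the glycine methyltransferase Gnmt (−4.59 ± 0.39), the amino acid transporter Slc38a5 (−4.38 ± 0.40) and Ggt1 of glutathione breakdown (−4.05 ± 0.39). Colipase, Clps, fell from 103000 ± 12800 to 5510 ± 1010 FPKM (−4.24 ± 0.69). Of 16 enzyme genes 13 fell, Cela3b (−2.98 ± 0.60) with it (camera adjusted p = 5.97e-05, adjusted p = 0.44 with an estimated correlation, camera adjusted p = 0.063 with quantile scaling). Of 19 macrophage markers 16 rose, with Cd68 (2.96 ± 0.33) and Ctss (3.14 ± 0.43) (camera adjusted p = 3.25e-08, adjusted p = 0.416 with an estimated correlation). Of 31 cell cycle genes 29 rose, with Top2a (2.47 ± 0.27) and Mcm6 (2.40 ± 0.21) (camera adjusted p = 1.39e-14, adjusted p = 0.276 with an estimated correlation). Of 19 fibroblast markers 15 rose, with Postn (3.32 ± 0.36) (camera adjusted p = 4.84e-06, adjusted p = 0.416 with an estimated correlation). Of 23 interferon-response genes 18 rose, with Irf7 (2.11 ± 0.50) (camera adjusted p = 3.48e-05, adjusted p = 0.44 with an estimated correlation). WT_24h replicate 1 had an interferon list mean of 3.55, against 2.09 and 2.35 in the others, and B and T cell list means of 2.73 and 2.33. Without it 7 interferon-response, 16 macrophage, 12 fibroblast and 28 cell cycle genes rose. Adipocyte list means were 0.83, 2.41 and 2.11 in WT saline and 4.14, 3.70 and 2.36 at 24 h, and with adipocyte and B cell covariates the same lists held 8, 14, 11 and 28 that rose. Of 26 ribosomal protein genes 22 fell, Rpl6 (−1.41 ± 0.18) most clearly (camera adjusted p = 1.29e-08, adjusted p = 0.44 with an estimated correlation). Of 23 unfolded protein and amino acid response genes 15 fell, with Dnajc3 (−2.02 ± 0.24) (camera adjusted p = 2.14e-06, adjusted p = 0.416 with an estimated correlation). Scaling to the total without enzyme and Reg genes gave 7892 calls (7448 up, 444 down) instead of 5013, and the spread of the compared groups alone gave 3170, and Reg3a was the 1 named gene whose call ended without a library. That scaling took the median of all genes from 0.05 to 0.721 here, from 0.064 to 0.851 in HET at 24 h, from 0.09 to 0.859 in HET at 48 h and from 0.03 to 0.397 for the genotypes at 48 h.

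In HET 3072 genes rose and 2529 fell at 24 h. Up were Cldn4, from 0.809 ± 0.611 to 244 ± 16.6 FPKM (7.14 ± 0.45, adjusted p = 4.42e-09), Chil3 (5.56 ± 0.80) and the granzyme inhibitor Serpinb9 (4.67 ± 0.31). Ccl2 (4.48 ± 0.35), Ccl7 (4.13 ± 0.30), Timp1 (4.45 ± 0.40), Tspan1 (4.30 ± 0.26) and Il1rn (4.05 ± 0.49) rose as well. Down were Serpini2 (−7.20 ± 0.92, adjusted p = 7.74e-06), Hamp2 (−7.19 ± 0.51), Tmed11 (−6.999 ± 0.47), Rnase1 (−6.30 ± 0.80), Gnmt (−5.60 ± 0.39), Clps (−5.58 ± 0.69), Zg16 (−5.52 ± 0.90) and Ctrc (−5.29 ± 1.28). Of 17 enzyme genes 15 fell (camera adjusted p = 2.59e-07, adjusted p = 0.468 with an estimated correlation). Of 11 acinar transcription factors 8 fell, with Bhlha15 (−5.03 ± 0.46) and Rbpjl (−3.44 ± 0.39) (camera adjusted p = 0.00104, adjusted p = 0.468 with an estimated correlation). Of 19 macrophage markers 15 rose and 1 fell, with Fcgr1 (3.69 ± 0.47) (camera adjusted p = 6.51e-05, adjusted p = 0.522 with an estimated correlation). Of 12 adipocyte markers 8 fell, with Fabp4 (−1.63 ± 0.42), beside list means of 3.35, 4.67 and 4.04 in the HET saline libraries and 1.40, 1.82 and 2.70 at 24 h (camera adjusted p = 0.00164, adjusted p = 0.611 with an estimated correlation). All 26 ribosomal protein genes fell, with Rps7 (−1.48 ± 0.24) (camera adjusted p = 3.74e-10, adjusted p = 0.468 with an estimated correlation). Scaled to the total without enzyme and Reg genes the count of 5601 became 8678 (8075 up, 603 down), and of 34 named genes the adipocyte marker Adrb3 alone lost its call without a library.

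At 48 h against saline, which asked what remained as tissue recovered, 1524 genes rose and 1735 fell in WT. Reg3g (5.02 ± 0.83, adjusted p = 0.000373), Reg3b (3.91 ± 0.89) and Reg3a (3.52 ± 1.15) stayed up. The tenascin Tnc rose from 0.0592 ± 0.026 to 21.8 ± 7.28 FPKM (4.38 ± 0.27). So did Thbs1 (3.85 ± 0.41, adjusted p = 4.79e-06), Postn (3.63 ± 0.36) and the collagen cross-linker Lox (3.50 ± 0.20). Ctrc (−4.15 ± 1.28), Pla2g1b (−3.55 ± 0.72), Slc38a5 (−3.12 ± 0.40), Tff2 (−3.03 ± 0.64), Clps (−3.00 ± 0.69), Zg16 (−2.82 ± 0.90), Ctrl (−2.78 ± 0.82) and Cuzd1 (−2.77 ± 0.46) fell. Of 17 enzyme genes 13 fell (camera adjusted p = 2.07e-05, adjusted p = 0.644 with an estimated correlation). Of 19 fibroblast markers 14 rose, with Tagln (3.12 ± 0.27) and Acta2 (2.93 ± 0.30) of contractile cells (camera adjusted p = 1.31e-11, adjusted p = 0.148 with an estimated correlation). Of 17 dedifferentiation markers 11 rose, with Cd44 (2.65 ± 0.31), and 1 fell (camera adjusted p = 1.02e-06, adjusted p = 0.0321 with an estimated correlation). Of 19 macrophage markers 13 rose, with Ms4a7 (2.78 ± 0.37) (camera adjusted p = 2e-08, adjusted p = 0.393 with an estimated correlation). Of 31 cell cycle genes 21 rose, with Cdk1 (2.61 ± 0.42) (camera adjusted p = 2.44e-10, adjusted p = 0.338 with an estimated correlation). Of 12 p53 targets 9 rose, with Phlda3 (2.72 ± 0.23) (camera adjusted p = 6.85e-06, adjusted p = 0.134 with an estimated correlation). All 5 red blood cell markers fell, with Hba-a1 (−2.24 ± 0.40) (camera adjusted p = 0.000621, adjusted p = 0.393 with an estimated correlation). The count of 3259 was 1840 without WT_48h replicate 2, 1089 without WT_48h replicates 1 and 2 (1 WT 48 h library against 3, with the spread of the other groups) and 1797 with the spread of the compared groups alone. Scaling to the total without enzyme and Reg genes gave 3628 up and 199 down. The calls of Reg3a, Ctrc, Zg16 and Ctrl ended without a single library. Of the genes that rose 734 of 1524, with Tnc, and of those that fell 561 of 1735 moved the same way against 8 h within the v2 guide (with the 48 h libraries in both), while 315 and 395 moved the other way. For these and the remaining genes guide and time cannot be told apart.

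In HET 3109 genes rose and 2575 fell at 48 h against saline. Cldn4 (6.199 ± 0.45, adjusted p = 1.81e-08), Tnc (4.70 ± 0.27), Timp1 (4.01 ± 0.40), Lcn2 (3.90 ± 0.45), Il1rn (3.71 ± 0.49), Serpinb6b (3.59 ± 0.38) and Mmp7 (3.31 ± 0.46) rose. The phospholipase Pla2g1b fell from 10100 ± 4980 to 81.8 ± 77.8 FPKM (−7.67 ± 0.72, adjusted p = 2.14e-07). Lower too were Zg16 (−7.61 ± 0.90), Pdia2 (−7.10 ± 0.71), Ctrl (−7.02 ± 0.82), Hamp2 (−6.89 ± 0.51), Tmed11 (−6.72 ± 0.47) and Rnase1 (−6.43 ± 0.80). All 18 enzyme genes tested fell (camera adjusted p = 2.55e-12, adjusted p = 0.311 with an estimated correlation), beside the enzyme share of 2.8% in HET_48h replicate 3. Of 11 acinar transcription factors 8 fell, with Gata4 (−1.61 ± 0.25) (camera adjusted p = 0.000138, adjusted p = 0.311 with an estimated correlation). All 26 ribosomal protein genes fell, with Rpl13 (−1.66 ± 0.22) (camera adjusted p = 2.18e-12, adjusted p = 0.352 with an estimated correlation). Of 23 unfolded protein and amino acid response genes 17 fell and 2 rose (camera adjusted p = 2.68e-08, adjusted p = 0.311 with an estimated correlation). Of 12 endothelial markers 9 fell, with Pecam1 (−0.99 ± 0.21) (camera adjusted p = 0.000275, adjusted p = 0.311 with an estimated correlation). Of 12 adipocyte markers 11 fell, with Retn (−3.30 ± 0.75) (camera adjusted p = 0.000239, adjusted p = 0.491 with an estimated correlation). Of 19 fibroblast markers 14 rose and 1 fell, with Col5a1 (2.56 ± 0.25) (camera adjusted p = 0.000103, adjusted p = 0.39 with an estimated correlation). Scaled to the total without enzyme and Reg genes the count of 5684 became 8859 (8268 up, 591 down), all 41 named genes kept their calls without any one library. Against 8 h 1333 of the 3109 that rose and 1043 of the 2575 that fell moved the same way and 764 and 317 the other way. For all but those that moved the same way guide and time cannot be told apart.

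Within the v2 guide, 48 h against 8 h followed the way back from the early response, with 2893 genes up and 3528 down in WT and 3007 and 3679 in HET. In WT Reg3g (8.62 ± 0.83, adjusted p = 1.26e-07), Reg3a (8.03 ± 1.15), Reg3b (7.11 ± 0.89), Reg2 (6.21 ± 1.07), Cckar (4.58 ± 0.40), Tnc (4.15 ± 0.27) and Acta2 (3.65 ± 0.30) rose. Of 6 Reg genes 5 rose in all (camera adjusted p = 0.00252, adjusted p = 0.738 with an estimated correlation). Rcan1 (−7.66 ± 0.17, adjusted p = 4.87e-17), Kel (−7.27 ± 0.29), Itpkc (−6.84 ± 0.29), Chac1 (−6.74 ± 0.46), Gclc (−5.70 ± 0.23), Krt8 (−5.27 ± 0.25) and Atf3 (−5.23 ± 0.24) fell again. The small RNA gene n-R5s202 was listed at 0 at 8 h and measured 19, 23.1 and 34.5 FPKM at 48 h, and Rny3 measured 63.9, 30.1 and 63.6 FPKM at 8 h and was listed at 0 at 48 h. In WT 16 of 20 AP-1 and immediate early genes fell (camera adjusted p = 4.12e-06, adjusted p = 0.738 with an estimated correlation). So did 10 of 11 heat shock genes, with Dnajb1 (−2.27 ± 0.22) (camera adjusted p = 4.88e-05, adjusted p = 0.738 with an estimated correlation). Of 19 fibroblast markers 14 rose, with Col5a1 (2.50 ± 0.25) (camera adjusted p = 5.26e-07, adjusted p = 0.738 with an estimated correlation). Of 19 macrophage markers 11 rose and 1 fell, with Adgre1 (2.18 ± 0.39) (camera adjusted p = 0.00374, adjusted p = 0.99 with an estimated correlation), a camera call that ended without WT_48h replicate 2 (adjusted p = 0.0571). In HET Reg3g (6.89 ± 0.83), Reg3a (6.31 ± 1.15), Reg3b (5.65 ± 0.89), Postn (4.55 ± 0.36), Col1a1 (4.19 ± 0.35), Fcrls (4.09 ± 0.20), Serpinb6b (3.97 ± 0.38) and Tnc (3.81 ± 0.27) rose. Chac1 (−7.36 ± 0.46), Kel (−7.36 ± 0.29), Itpkc (−6.87 ± 0.29), Rcan1 (−6.40 ± 0.17), Arc (−5.93 ± 0.26), the substance P gene Tac1 (−5.76 ± 0.32), Dusp5 (−5.71 ± 0.24) and Pdia2 (−5.64 ± 0.71) fell. All 19 enzyme genes tested fell between 8 h and 48 h in HET (camera adjusted p = 5.05e-05, adjusted p = 0.809 with an estimated correlation). Of 31 cell cycle genes 30 rose, with Birc5 (2.53 ± 0.25) (camera adjusted p = 3.54e-11, adjusted p = 0.464 with an estimated correlation). Fibroblast markers rose in 15 of 19 (camera adjusted p = 1.45e-07, adjusted p = 0.464 with an estimated correlation). AP-1 and immediate early genes fell in 16 of 20 (camera adjusted p = 2.21e-05, adjusted p = 0.809 with an estimated correlation). Scaling to the total without enzyme and Reg genes gave 4986 up and 1433 down in WT and 6692 up and 1185 down in HET. Of the named genes n-R5s202 alone lost its call without a single library.

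Interactions asked whether the response to caerulein itself differed between genotypes. At 8 h 3 genes passed, of which St18, a zinc finger transcription factor, had the larger response in HET (1.69 ± 0.27, adjusted p = 0.025). The others, named after their values were seen, were Gm11032, at 34.8 ± 6.78 FPKM in WT at 8 h and listed at 0 in HET at 8 h and in saline, and GM13989, at 5.82 ± 3.09 FPKM in HET at 8 h and listed at 0 in WT at 8 h and in saline. Of 100 exchanges of genotype labels 36 gave at least 3 genes. At 24 h 296 genes passed, 138 with a larger and 158 with a smaller value in HET. Scaling to the total without enzyme and Reg genes gave 32 and 13, and the spread of the compared groups alone 38 and 63. Leaving out 1 library gave 130 (without WT_24h replicate 1) to 616 (without WT_24h replicate 3). Cldn4 went from 1.71 ± 0.89 to 26.6 ± 12.6 FPKM in WT and from 0.809 ± 0.611 to 244 ± 16.6 FPKM in HET (3.83 ± 0.64, adjusted p = 0.00949). Scd1 went from 13.1 ± 7.42 to 44 ± 27.2 FPKM in WT and from 133 ± 92.9 to 10.1 ± 5.24 FPKM in HET (−5.08 ± 1.00, adjusted p = 0.0139). Of 12 adipocyte markers 4 had a lower response in HET and all 12 over the list alone, at a median of −3.83 (camera adjusted p = 5.02e-12, adjusted p = 0.351 with an estimated correlation). Of 19 fibroblast markers 4 had a lower response in HET and 12 over the list alone (camera adjusted p = 1.5e-10, adjusted p = 0.351 with an estimated correlation). Of 9 acute phase genes the counts were 2 and 6 (camera adjusted p = 4.92e-05, adjusted p = 0.449 with an estimated correlation). At 48 h 154 genes passed, 41 with a larger and 113 with a smaller value in HET. That split turned to 16 and 7 under the same scaling and to 6 and 3 with the spread of the compared groups alone. Leaving out 1 library gave 58 (without WT_48h replicate 3) to 383 (without WT_48h replicate 2), and leaving out WT_48h replicates 1 and 2 gave 31, with 1 WT library left. Tmed11 went from 298 ± 46 to 63.7 ± 30.5 FPKM in WT and from 278 ± 80.3 to 2.3 ± 2.6 FPKM in HET (−4.41 ± 0.66, adjusted p = 0.00539). Of the enzyme genes tested 3 of 17 had a lower response in HET and 16 over the list alone (camera adjusted p = 1.06e-14, adjusted p = 0.34 with an estimated correlation). Of 12 adipocyte markers 2 had a lower response and 10 over the list alone (camera adjusted p = 1.62e-09, adjusted p = 0.34 with an estimated correlation). Of 17 cholesterol synthesis genes 1 had a lower response and 6 over the list alone (camera adjusted p = 7.3e-06, adjusted p = 0.34 with an estimated correlation). With the adipocyte and B cell list means as covariates limma called 0 genes at 24 h (1594 at an unadjusted p under 0.05, 2281 in the main fit) and 6 at 48 h. At 24 h the median absolute log2 fold of genes with smaller values in HET went from 1.62 to 1.02. For larger values it went from 1.08 to 1.09. Standard errors grew (0.36 to 0.426 and 0.241 to 0.338). At 48 h these medians of main calls stayed, at 1.05 and 1.09 for larger and 1.74 and 1.79 for smaller values before and after. Standard errors grew (0.235 to 0.318 and 0.356 to 0.463). Without any one library 11 of the 22 named genes kept their call at 24 h (Cldn4, Cxcl14, Il4i1, Camk2d, Cdh1, Krt23, Car8, Scd1, Thrsp, Lrg1 and Fabp4) and 9 of the 20 at 48 h (Il4i1, Nt5dc2, Gabrp, Cdh1, Thrsp, Tmed11, Hamp2, Fasn and Insig1), and St18 did not keep its call.

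Across 12835 genes the saline genotype difference and the WT 24 h response had Pearson r = 0.512 and Spearman rho = 0.519. Both share the WT saline libraries. Noise simulated with these alone gave r = 0.517 (0.153 to 0.734), so r cannot be read. Covariance was 0.219 (simulated 0.0186 to 0.154) but −0.0472, within −0.15 to −0.0119, for the HET 24 h response. Genotype differences at different times share no library. At 24 h and 48 h they had r = 0.45 (exact one-sided p = 0.005 over 200 exchanges of labels, adjusted p = 0.03 over 6 pairs). At these times 211 genes were higher and 212 lower in both, where independent calls give 26.5 and 24.5. At 8 h and 48 h r was 0.251 (adjusted p = 0.03), at saline and 8 h 0.205 (adjusted p = 0.03), at 8 h and 24 h 0.147 (adjusted p = 0.0825) and at saline and 24 h −0.031 (exact p = 0.645).

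**Figure D3:**
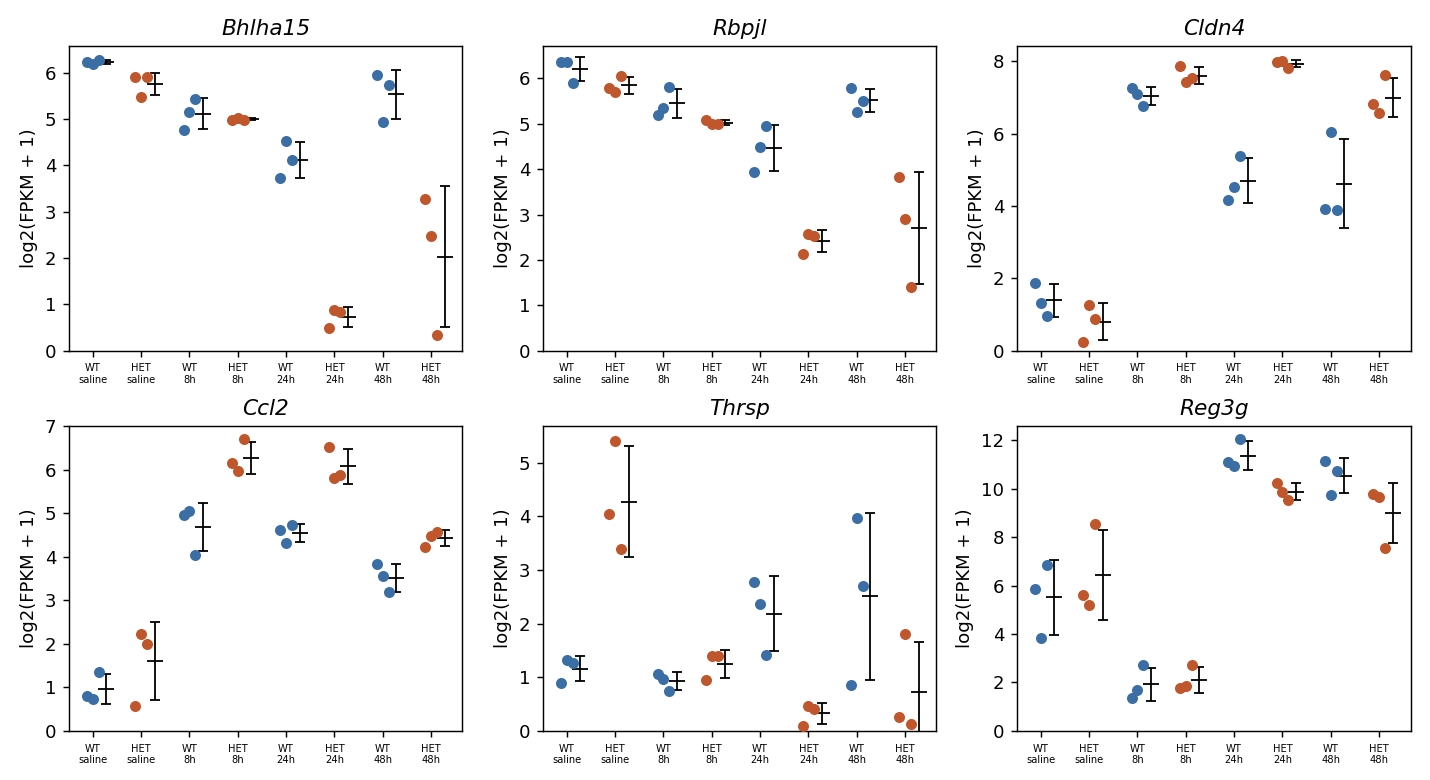
The log2(FPKM + 1) of Bhlha15, Rbpjl, Cldn4, Ccl2, Thrsp and Reg3g is plotted per library as points for the 8 groups, with the mean and SD of 3 animals. Bhlha15 measured 74.3 ± 2.56 FPKM in WT saline and 0.674 ± 0.243 FPKM in HET at 24 h.

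Several named genes lie in families of near-identical copies (trypsinogens, kallikreins, Reg3, globins) or overlap a neighbour, and the strand of the libraries was not stated, so that their values may mix copies.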

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

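Tests of fat and lymphoid tissue in each direction alone, of 1 library, of dilution, of RNA mixing and of an XXY animal were chosen after the results were seen, as were the adipocyte and B cell covariates, and the others before.

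Responses that differed between genotypes by the interaction test itself were 3 genes at 8 h, 296 at 24 h and 154 at 48 h. At 8 h St18 had a value of 1.69 (HET response minus WT response, log2). At 24 h the largest positive values were Cldn4 3.83, Cxcl14 2.41, Il4i1 2.18, Tcim 2.16, Camk2d 2.16, Cdh1 2.09, Krt23 1.97 and Car8 1.85. The largest negative values were Scd1 −5.08, Thrsp −4.97, Trf −3.83, Plin1 −3.73, Dgat2 −3.45, Nnat −3.30, Lrg1 −3.28 and Fabp4 −3.24. At 48 h they were Cldn4 2.97, Il4i1 2.41, Nt5dc2 1.91, Gabrp 1.68, Cxcl14 1.62, Car8 1.49, Cdh1 1.48 and Lrrc42 1.45, and on the negative side Thrsp −4.90, Tmed11 −4.41, Pdia2 −4.38, Hamp2 −4.16, Tmed6 −3.78, Try10 −3.78, Fasn −3.51 and Retnla −3.35. List medians were −3.83 for adipocyte, −1.44 for fibroblast and −2.36 for acute phase genes at 24 h, and −3.38 for digestive enzymes, −3.12 for adipocyte and −0.49 for cholesterol synthesis genes at 48 h.

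The saline genotype difference (303 genes) was weighed against carried-over tissue, sex and preparation. With adipocyte and B cell list means as covariates 9 genes passed, because folds shrank and standard errors grew. Genes lower in HET kept 0.9 of their median absolute log2 fold (0.85 to 0.95 without 1 library, from 0.71 to 0.64, SE 0.156 to 0.212) and all calls 0.84 (0.76 to 0.88). This argues against fat and lymphoid tissue as the whole cause. Genes higher in HET kept 0.72 (0.69 to 0.81, from 1.02 to 0.74, SE 0.221 to 0.277), which leaves it open. A sex covariate left a share of 0.96 (0.89 to 1) and leaving out WT_saline replicate 3 left 1.04, which argue against sex of the animals and preparation under an unlisted guide. Loss of an Nr5a2 copy stays open, beside fat and lymphoid tissue for higher genes. Islet content was not tested.

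Lower digestive enzyme transcripts in HET at 48 h (median −3.59) were weighed against 1 library, dilution and scaling. Without HET_48h replicate 3 the median was −2.3 and 20 of 24 genes still passed. All 24 had both other HET libraries below every WT library, a shared order that chance gives in 10% of cases. Dilution by all other cells would raise their markers alike, by 1 or some cell types theirs alone. Macrophage minus endothelial list means differed by 1.66 (WT 0.48 to 2.16, HET 2.53 to 3.55). Medians were 1.23 (macrophage), 0.35 (fibroblast), 0.03 (duct), −0.5 (endothelial) and −0.66 (islet). Scaling left medians of −2.88 to −3.61. These values argue against each but dilution by 1 cell type as the whole cause. Loss of an Nr5a2 copy as the cause is a hypothesis, found and tested on the same data.

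Xist, made from the inactive X of females, stood at 20.5 FPKM in WT_48h replicate 2 beside Y-linked Ddx3y (1.06 FPKM) and Eif2s3y (3.71 FPKM). Ddx3y, Eif2s3y, Uty and Kdm5d stood at 0.34, 0.33, 0.25 and 0.34 of the median of the other Y-carrying 48 h libraries. An animal with 2 X chromosomes and a Y would carry them in full, and the highest share of 0.34 argues against that. RNA of another animal in the library may be the source, with a lowest share of 0.25. No other biological explanation was tested.

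For 3 animals against 3 only 10 groupings exist, too few for a share under 0.05. The real count and the highest of the others were 301 and 33 for genotypes in saline, 28 and 5 at 8 h, 839 and 2 at 24 h, and 1560 and 22 at 48 h, with 1 grouping, the real one, reaching the real count. For WT they were 6540 and 1 at 8 h, 5013 and 11 at 24 h, 3257 and 2 at 48 h, and 6412 and 4 for 48 h against 8 h. For HET they were 7091 and 2, 5600 and 1, 5672 and 1, and 6673 and 2. For the mean genotype difference 1 of 100 groupings reached 2392 (highest other 11), so chance was excluded. For the 24 h interaction 2 of 100 reached 295 (highest other 392, with real 24 h labels). For the 8 h interaction 36 of 100 reached 3 (highest other 27), so chance was not excluded. For the 48 h interaction 12 of 100 reached 152 (highest other 1805). Of the 11 others 10 had real 48 h labels. Such exchanges held that genotype difference, so they cannot settle chance at 24 h or 48 h.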

How the results depend on the processing

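Keeping zeros of abundant genes as deposited, protein-coding genes only, adipocyte and B cell covariates and leaving out both WT_48h libraries with Xist and Y-linked transcripts were chosen after the data were seen. Of the counts per comparison and 1 correlation, 285 values under an alternative stayed within 1.5 times (the correlation within its jackknife SE) and 66 moved. Of list calls 996 stayed and 97 ended, and of named gene values 1867 stayed on their side of the threshold, 156 ended and 1 reversed, Nr5a2 at 48 h, from −0.39 to 0.016 under scaling to the total without enzyme and Reg genes (adjusted p = 0.97, range over alternatives 0.147 to 0.97). The counts of the mean genotype difference, of 8 h against saline and of 48 h against 8 h in either genotype moved by less than 1.5 times under every alternative run.

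Scaling to the total without enzyme and Reg genes changed the genotype counts from 303 to 11 in saline, 28 to 10 at 8 h, 841 to 528 at 24 h and 1572 to 3509 at 48 h. It changed 24 h against saline from 5013 to 7892 in WT and from 5601 to 8678 in HET, HET 48 h against saline from 5684 to 8859, and the interactions from 3 to 1 (0 higher, 1 lower), 296 to 45 (32 higher, 13 lower) and 154 to 23 (16 higher, 7 lower). Quantile scaling gave 181 in saline, 14 at 8 h and 291 for the 48 h interaction. A spread from the compared groups alone, with fewer degrees of freedom, gave 1 in saline, 4 at 8 h, 258 at 24 h, 28 at 48 h, 3170 for WT 24 h, 1797 for WT 48 h, 101 for the 24 h interaction and 9 for the 48 h interaction. A pseudocount of 0.1 gave 5 genes at 8 h and 1 for the 8 h interaction, no filter gave 6 for that interaction, and zeros as deposited gave 10. With the adipocyte and B cell covariates limma called 9 genes in saline, 16 at 8 h, 0 for the 24 h interaction (1594 at an unadjusted p under 0.05, smallest adjusted p = 0.079) and 6 for the 48 h interaction. For both interactions the folds and errors are given with the results. Without both WT_48h libraries that held Xist and Y-linked transcripts, which left 1 library in that group and its spread to the other groups, the counts were 487 for genotypes at 48 h, 1089 for WT 48 h and 31 for the 48 h interaction. HET_48h replicate 1, with Xist at 1.23 FPKM beside Y-linked transcripts, against 2.08 FPKM in WT_48h replicate 1, was kept there. List calls went from 199 to 1 with an estimated correlation. Except for fewer libraries, fewer degrees of freedom and the larger errors given, the cause was not tested.

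Leaving out each library in turn gave 117 to 435 genes for genotypes in saline (117 without HET_saline replicate 2, 150 without WT_saline replicate 1, 192 without WT_saline replicate 3) and 5 to 27 at 8 h (5 without HET_8h replicate 1, 9 without WT_8h replicate 3 or HET_8h replicate 3, 16 without HET_8h replicate 2). At 24 h it gave 309 to 800 (309 without HET_24h replicate 1, 412 without WT_24h replicate 2, 474 without HET_24h replicate 2, 495 without HET_24h replicate 3) and at 48 h 474 to 2255 (474 without WT_48h replicate 1, 487 without HET_48h replicate 3, 657 without WT_48h replicate 3, 868 without HET_48h replicate 2). WT 48 h against saline ranged from 1840 (without WT_48h replicate 2) to 3389. The 8 h interaction ranged from 2 to 16 (12 without WT_saline replicate 2, 16 without HET_saline replicate 3, 5 without WT_8h replicate 1, 6 without WT_8h replicate 2). The 24 h interaction ranged from 130 to 616 (130 without WT_24h replicate 1, 155 without HET_24h replicate 1 or 2, 173 without WT_24h replicate 2, 178 without HET_24h replicate 3, 181 without HET_saline replicate 2, 447 without HET_saline replicate 1, 616 without WT_24h replicate 3). The 48 h interaction ranged from 58 to 383 (58 without WT_48h replicate 3, 63 without HET_48h replicate 3, 77 without WT_48h replicate 1, 82 without WT_saline replicate 1, 383 without WT_48h replicate 2). The correlation of the saline genotype difference with the WT 24 h response ranged from 0.399 (without HET_saline replicate 2) to 0.582 (without WT_saline replicate 3), with a jackknife SE of 0.117 over the 9 libraries in it. Depth is unknown, so counting error could not be set beside these ranges.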

Other observations

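The test on linked alleles was chosen after the result was seen, and the test on a profile before caerulein was not.

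Of 14 circadian clock genes 3 were lower in HET on average over conditions, Dbp (−0.76 ± 0.12, adjusted p = 0.000224), Nr1d1 (−0.54 ± 0.15) and Arntl (−0.22 ± 0.07), and 4 over the list alone (camera adjusted p = 0.0655, adjusted p = 0.442 with an estimated correlation). Of 13 duct markers 3 were higher in HET, with the keratin Krt19 (0.65 ± 0.11, adjusted p = 0.000554), and 2 lower (camera adjusted p = 0.675, adjusted p = 0.829 with an estimated correlation). Of 16 complement genes 7 were higher in HET on average, with the receptors C5ar1 (1.07 ± 0.18) and C3ar1 (0.66 ± 0.13) (camera adjusted p = 0.00953, adjusted p = 0.569 with an estimated correlation). In WT at 24 h against saline 2 of 10 MHC class II genes (camera adjusted p = 0.0294, adjusted p = 0.538 with an estimated correlation) and 4 of 7 mesothelial markers (camera adjusted p = 0.0352, adjusted p = 0.511 with an estimated correlation) rose. None of 10 B cell markers (median 0.71, camera adjusted p = 0.174, adjusted p = 0.675 with an estimated correlation) and none of 5 T cell markers passed there (camera adjusted p = 0.5, adjusted p = 0.734 with an estimated correlation). None of 5 sex-linked transcripts, a list not put to camera, passed there (median 0.03).

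A hypothesis was that genes near Nr5a2 might carry linked alleles of the targeted strain. Among the 100 tested genes nearest to Nr5a2 26 differed in the mean genotype comparison, against 2270 of 11841 others (19.2%), a ratio of 1.36 (0.93 to 1.86, Fisher's exact p = 0.097), which left the question open.

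Another hypothesis was that the genotype profile at 48 h might already be present before caerulein. Across 12835 genes the saline and 48 h genotype differences had r = 0.162, below the highest value of 0.376 among the other exchanges of genotype labels (exact one-sided p = 0.14). Spearman rho was 0.261, and of genes called at both times 36 were higher and 40 lower in both (8.6 and 9.8 if independent) against 2 and 0 in opposite directions. A value inside that range had been set beforehand as evidence against the hypothesis, but it excludes no shared part, which these counts may reflect, so the question stayed open.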
